A study of Mus musculus with 3 samples.

How the data were processed

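TBX5 ChIP-seq was made from whole lungs dissected from CD-1 mouse embryos at stage E14.5, with 2 ChIP libraries, called biological replicates in the series design, and 1 input library. Per the labels' protocols, tissue was cross-linked with formaldehyde, sonicated and precipitated with an antibody to TBX5, with 1 whole lung per replicate. Per the series design, fragments were selected by size and read from a single end on Illumina instruments. Groups were taken from the titles, which name lung for all 3 libraries, although the source field names heart for ChIP library 2 and for the input.

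The deposited data were 1 list of peaks in the layout that MACS2 writes, and no value of any single library was used. Bowtie2, SAMtools and MACS2 and build mm10 are named per the submitters' processing notes, and their versions and settings are not given in the sources used here. Whether the ChIP libraries were merged before peaks were called, and whether the input served as the control, is not given in the sources used here either. The name of the deposited list says that blacklisted regions were removed, and 23 of the 28404 peak numbers were absent from it. For each peak the authors' caller gave a fold enrichment, the ratio of ChIP signal at the summit to its local background. It also gave the −log10 of a q-value at the summit, as deposited by the authors. The score deposited by the authors equalled the integer part of 10 times that −log10 q in 98.8% of peaks and differed from it by at most 1 in the rest. The deposited summit offset, in bp from the start of the peak, gave the position used for each peak. The units come from the layout and the values, since the list has no header. Starts are given 1-based. A fold over a local background depends on the depth of ChIP and control libraries, which is unknown here, so peaks were ranked only within this list. A peak called on merged libraries need not be present in both.

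Genes came from a RefSeq table of assembly GRCm38.p6, the assembly of build mm10, with 21631 protein-coding genes on the chromosomes used. That table gives the first and last base of each gene, without strand, exons or sequence. The tests fixed before the data were examined had assumed gene starts, exons and a genome sequence. In their place, the promoter share became the share of summits within 1 kb of either end of a protein-coding gene, the intron share became the share inside genes, and the distance to a gene start became the distance to the nearer gene end. The tests of 27 sequence motifs, the T-box half-site among them, were not run. Gaps in the assembly could not be excluded, and random positions were drawn between the first and last annotated or peak base of each chromosome.

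Summits were compared with 1000 random placements within their own chromosome, keeping the number per chromosome. A two-sided permutation p was taken as the smaller tail doubled, so the smallest p is 0.002. The difference in log2 fold between gene-end and other peaks was tested with 100000 permutations. Each peak was assigned to the protein-coding gene with the nearest end, if within 100 kb. A gene's territory is the stretch in which a peak would be so assigned. For the 5000 peaks with the highest −log10 q, the share of a list's genes with such a peak was compared with 10000 random lists whose genes were drawn from the 100 genes closest in territory length, with a smallest p of 0.0002, and adjusted by Benjamini-Hochberg over 18 lists. The lists held 444 different genes, of which 1 stood in more than 1 list, and all were matched by symbol except 1 matched by synonym. Shares carry exact 95% binomial intervals and peak densities exact 95% Poisson intervals, which cover counting error only. Differences between lists were tested with the same matched lists and with Fisher's exact test, adjusted over 8 comparisons.

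Lists, tests, thresholds and the rule for named genes were fixed before the data were examined, except that the comparisons of fold by position and between lists, and the tests of gene families, gene types, both ends of genes and contractile genes with the dense windows, were added after the data were seen. The choice of −log10 q as the value for ranking was made when the list was in hand, and the use of gene ends when the gene table was. Named were the genes assigned to the 10 peaks with the highest −log10 q, the 10 genes with the most assigned peaks, the 2 members of each list with the highest peak, and 20 genes always given: Tbx5, Tbx4, Tbx2, Tbx3, Aldh1a2, Rdh10, Wnt2, Wnt2b, Shh, Gli1, Ptch1, Hhip, Fgf10, Bmp4, Foxf1, Nkx2-1, Nppa, Nkx2-5, Gata4 and Alb, 66 genes in all, of which 1 is not reported here. Alternatives tried were fewer or all peaks, autosomes only, all annotated genes, other windows and distances, other assignments and unmatched lists. A further 5 were added after the data were seen: ranking by fold, assignment to the nearest gene body, leaving out gene-end peaks, a binomial test over territory length, and placements near genes.

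The list test was checked on 100 simulated sets of strong peaks placed at random over the 21631 genes. It called 3% of lists of 25 random genes, and 100% of lists in which 10 of the 25 genes were given a peak. Simulated peaks were placed independently and simulated genes drawn at random, while the real peaks lay in groups and some lists hold neighbouring genes. The 3% therefore need not hold for such lists, and the 100% applies only to an excess of that size. The nearest gene end equalled that of an exhaustive search at 100% of tested positions. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.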

Results

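Genomic regions bound by TBX5, a T-box transcription factor of the heart, forelimb and lung mesenchyme, were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole lungs of CD-1 mouse embryos at E14.5, a stage of embryonic development when the airways are branching. The series held 2 libraries made with an antibody to TBX5, each from 1 whole lung, and 1 library of input chromatin. These 3 libraries are represented by 1 deposited list of peaks, with no value per library. No spread between the 2 ChIP libraries could therefore be measured, no library could be left out in turn, and the depth of the libraries is unknown. The titles of all 3 libraries name lung, and the shared protocol describes lung, but the source field names heart for ChIP library 2 and for the input. The question asked of the list was where in the genome, and beside which genes, TBX5 was found in the fetal lung.

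The list held 28381 peaks on the 19 autosomes and chromosome X of mouse genome build mm10, covering 9.80 Mb. Peaks had a median width of 291 bp (range 189 to 1979 bp). The fold enrichment at the summit, as given by the authors' peak caller, had a median of 6.27 and ranged from 1.86 to 99.0. There were 6014 peaks (21.2%) at or over 10-fold, 81 at or over 50-fold, and 6743 (23.8%) under 5-fold. The fold and −log10 q of each peak are the authors' values and were used only to describe and rank peaks within this list. The 5000 peaks with the highest −log10 q, called strong peaks here, had a −log10 q of at least 21.4 and a median fold of 16. Their lowest fold was 3.59, so a strong peak need not have a high fold. The highest or strongest peak of a gene or list is the one with the highest −log10 q, which need not have the highest fold.

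The peak with the highest −log10 q lay inside the growth hormone receptor gene Ghr, on chromosome 15 from 3580017 to 3581049, 2.86 kb from the nearer gene end, with 99.0-fold enrichment. Among the 10 highest peaks, those inside genes also included Nrde2 (65.3-fold), Skap1 (77.2-fold), Mipep (86.2-fold) and Ror1, which encodes a receptor for Wnt ligands (84.7-fold). A peak of 84.9-fold lay 47.1 kb outside A430057M04Rik. The other 4 of the 10 had no protein-coding gene end within 100 kb. These were on chromosome 4 from 81744456 to 81745415 (93.3-fold), chromosome 1 from 184221762 to 184222412 (90.2-fold, 146 kb from Dusp10), chromosome 12 from 9847024 to 9848600 (91.4-fold, 266 kb from Osr1) and chromosome 10 from 111695878 to 111696866 (69.8-fold, 188 kb from Phlda1).

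TBX5 peaks were found at the ends of protein-coding genes far more often than randomly placed positions were, but most peaks lay elsewhere. Of the 28381 summits, 4981 (17.6%, exact 95% binomial interval 17.1 to 18%) lay within 1 kb of an end of a protein-coding gene, either the first or the last annotated base. Random placement within the same chromosomes gave 3.10% (middle 95% of 1000 placements, 2.90 to 3.30%), a ratio of 5.67 with a two-sided permutation p of 0.002, the smallest that 1000 placements allow. From 1 to 5 kb the share was 9.74% against 9.66% in the placements (permutation p = 0.671), made up of 3.78% against 2.73% from 1 to 2 kb and 5.96% against 6.92% from 2 to 5 kb, which were not tested separately. A further 11753 summits (41.4%) lay inside a gene and over 1 kb from its ends, and 11647 (41.0%) lay between genes, against 38.7% and 58.2% in the placements (permutation p = 0.002 for each). The median distance to a gene end was 27786 bp, against 48824 bp in the placements (permutation p = 0.002). Random positions could fall in gaps of the assembly and in unmappable sequence. This may raise the placed share between genes and the placed distance, by an amount that was not measured. Of the ribosomal protein genes, which every cell uses, 48.6% had a peak at an end, against 21.9% in matched random lists (permutation p = 0.0004). The annotation used here gave no strand and no exons, so the starts of genes could not be told from their last bases, and introns were not separated from exons. It also gave no starts of transcripts between those bases, and any peak at such a start was counted as inside the gene.

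**Figure D1:**
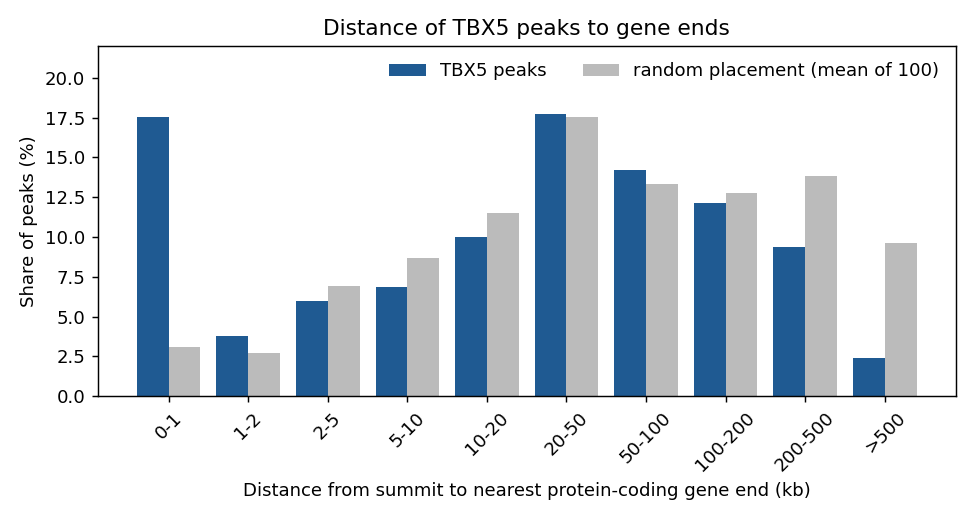
Share of TBX5 peak summits (y axis, %) by distance to the nearest end of a protein-coding gene (x axis, kb), with the mean of 100 random placements in grey. The bin within 1 kb held 17.6% of peaks against 3.09%, that from 1 to 2 kb 3.78% against 2.73%, and that beyond 500 kb 2.41% against 9.60%.

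Peaks at gene ends were weaker than peaks elsewhere. The median fold was 5.49 (quartiles 4.51 and 7.03) within 1 kb of a gene end, 6.59 inside genes and 6.60 between genes. The mean log2 fold was 2.55 at gene ends and 2.91 elsewhere, a difference of −0.36 (permutation p = 2e-05, the smallest that 100000 resamples allow). Strong peaks made up 8.21% of gene-end peaks (exact 95% binomial interval 7.46 to 9.01%), 19.3% of those inside genes (18.6 to 20.05%) and 19.9% of those between genes (19.2 to 20.7%). With the list split by −log10 q into 4 parts of equal size, 9.91% of summits lay at gene ends in the part with the highest values, against 19.3%, 20.6% and 20.4% in the others. Peaks are not independent replicates, and these comparisons describe this list.

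TBX5 peaks also lay close to each other. Of all peaks, 50.1% had another summit within 10 kb, against 20.5% of randomly placed peaks (permutation p = 0.002), and 82.1% had another within 50 kb, against 67.7% (permutation p = 0.002). The random positions were spread evenly over each chromosome, gaps in the assembly included, and were not limited to regions active in lung. Any set of regions that is unevenly spread would exceed them, so this excess need not be particular to TBX5. Genes with the most assigned peaks, where a peak was assigned to the protein-coding gene with the nearest end within 100 kb, included Nfib (33 peaks), Tbx5 (30), Rad51b (29), Bcas3 (23), Zeb2 (23), Ptch1 (22), Tgfbr3 (22), Tns3 (22) and Lrmda (21). Nfib, Tbx5 and Zeb2 encode transcription factors, Ptch1 the hedgehog receptor and Tgfbr3 a TGF-beta co-receptor. The counts were not scaled by the stretch in which a peak would be assigned to the gene. For these genes it ran from 170.6 kb (Ptch1) to 400 kb (Nfib), and genes with long stretches collect more peaks by chance. Assigning peaks to the nearest gene body raised Lrmda to 69 peaks, Rad51b to 53 and Bcas3, whose body ends next to Tbx2, to 44. With a limit of 1 Mb in place of 100 kb, Nfib had 50 peaks, Rad51b 59, Bcas3 44, Zeb2 42 and Lrmda 69. The order of these genes also depended on weak peaks: among the 14191 peaks with the highest −log10 q (50% of the list), Rad51b had 18, Tgfbr3 16, Nfib 15, Bcas3 14, Ptch1 13, Tbx5 11, Tns3 11, Lrmda 11 and Zeb2 9.

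The loci of Tbx5, Tbx4, Tbx2 and Tbx3 carried 10 to 30 peaks each. The T-box family as a whole, examined after the list had been seen, did not depart from matched random lists: 4 of 17 genes had a strong peak (23.5% against 17.3%; permutation p adjusted over 17 families = 0.887). Tbx5 itself had 30 assigned peaks, 6 of them strong, spread over the flank below the first base of the gene and through its body on chromosome 5 (119796514 to 119885220). Its peak with the highest −log10 q lay inside the gene from 119834301 to 119834932 (17.3-fold), and its peak with the highest fold from 119810745 to 119811823 (22-fold). No Tbx5 peak lay within 1 kb of the first or last annotated base of the gene. Starts of transcripts between those bases were not known, so whether a peak lay at a Tbx5 promoter could not be told. Tbx4, the paralogue also active in lung mesenchyme, had 10 peaks, 3 of them strong, with the strongest inside the gene on chromosome 11 from 85893572 to 85894394 (53.8-fold). Tbx2 had 12 peaks, 5 of them strong, and its strongest covered a gene end from 85832040 to 85833139 on chromosome 11 (28.6-fold). Tbx3 had 17 peaks, 3 of them strong, the strongest at a gene end on chromosome 5 from 119670216 to 119671709 (23.7-fold), while a peak of 24.5-fold lay 2.83 kb outside the gene from 119667464 to 119668458. With a limit of 1 Mb, Tbx3 had 39 peaks. Among the 14191 highest peaks, Tbx5 and Tbx3 had 11 each, Tbx2 8 and Tbx4 6. The list gives no error for these counts, and they were not scaled by territory, which ran from 34.8 kb for Tbx2 to 244.6 kb for Tbx5.

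**Figure D2:**
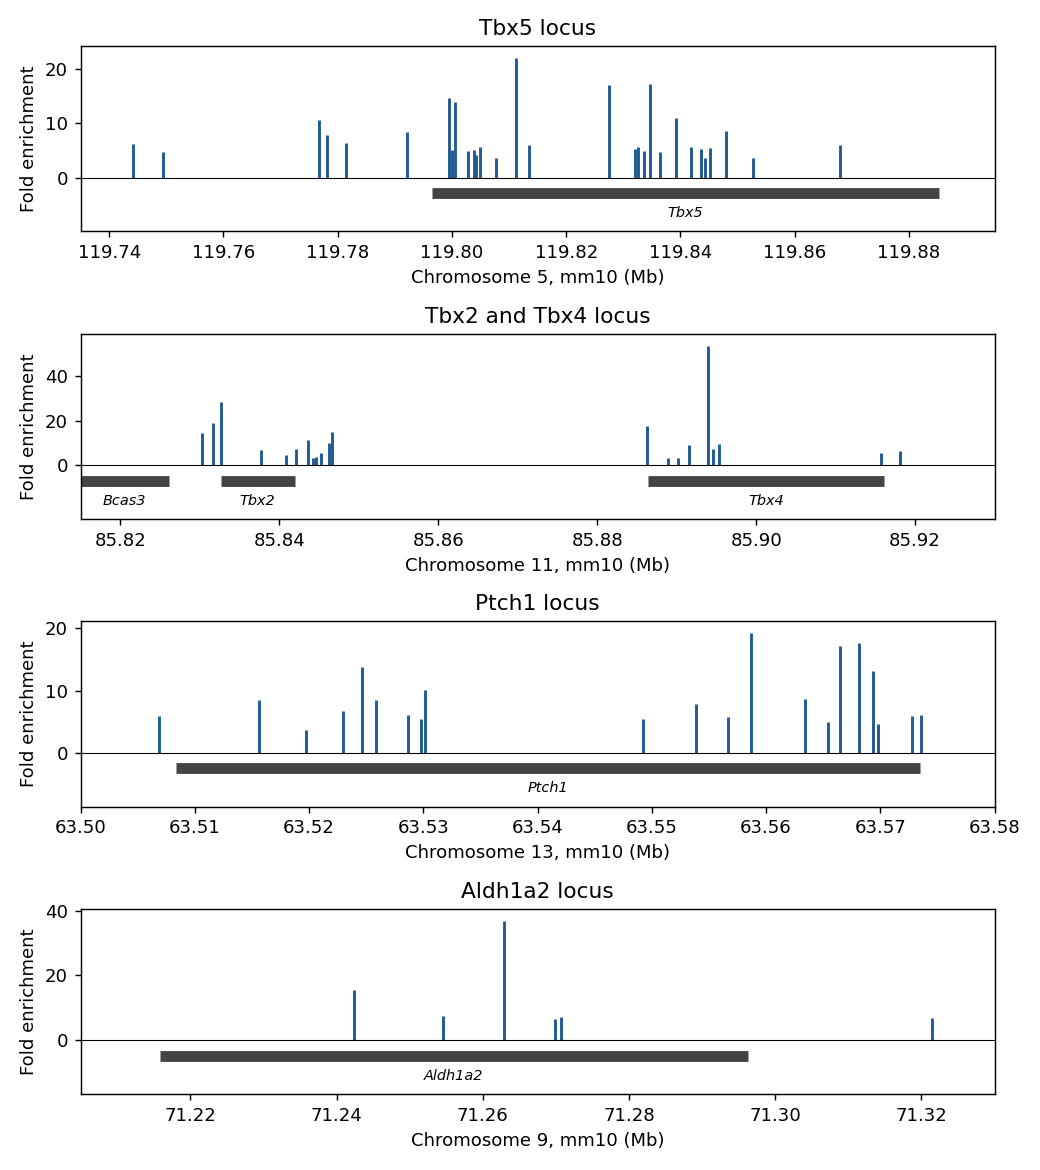
Fold enrichment at the summit (y axis) of every TBX5 peak against position (x axis, Mb, build mm10) at Tbx5, at Tbx2 and Tbx4, at Ptch1 and at Aldh1a2, with protein-coding genes drawn to scale as bars. The highest peaks reach 22-fold at Tbx5, 53.8-fold at Tbx4, 19.2-fold at Ptch1 and 36.9-fold at Aldh1a2.

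Strong TBX5 peaks lay near the genes of lung mesenchyme, its matrix and smooth muscle, and of the hedgehog, FGF, BMP and TGF-beta, and Wnt pathways, more often than near genes with stretches of surrounding sequence of the same length. Across the genome, 21605 peaks (76.1%) were assigned to a gene, and 8608 of 21631 protein-coding genes (39.8%) had a peak and 2361 (10.9%) a strong peak. For each of 18 gene lists the share of members with a strong peak was set against 10000 random lists matched gene by gene on territory, the stretch in which a peak would be assigned to the gene. In a two-sided permutation test, 7 lists lay above their matched lists and 0 below at an adjusted p (Benjamini-Hochberg over the 18 lists) under 0.05. The random lists were not matched on the activity of the genes in lung. Some lists hold neighbouring genes, such as Tbx2 and Tbx4 or Col3a1 and Col5a2, while the random lists draw genes independently. The p-values of such lists may therefore be too small, by an amount that was not measured.

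**Figure D3:**
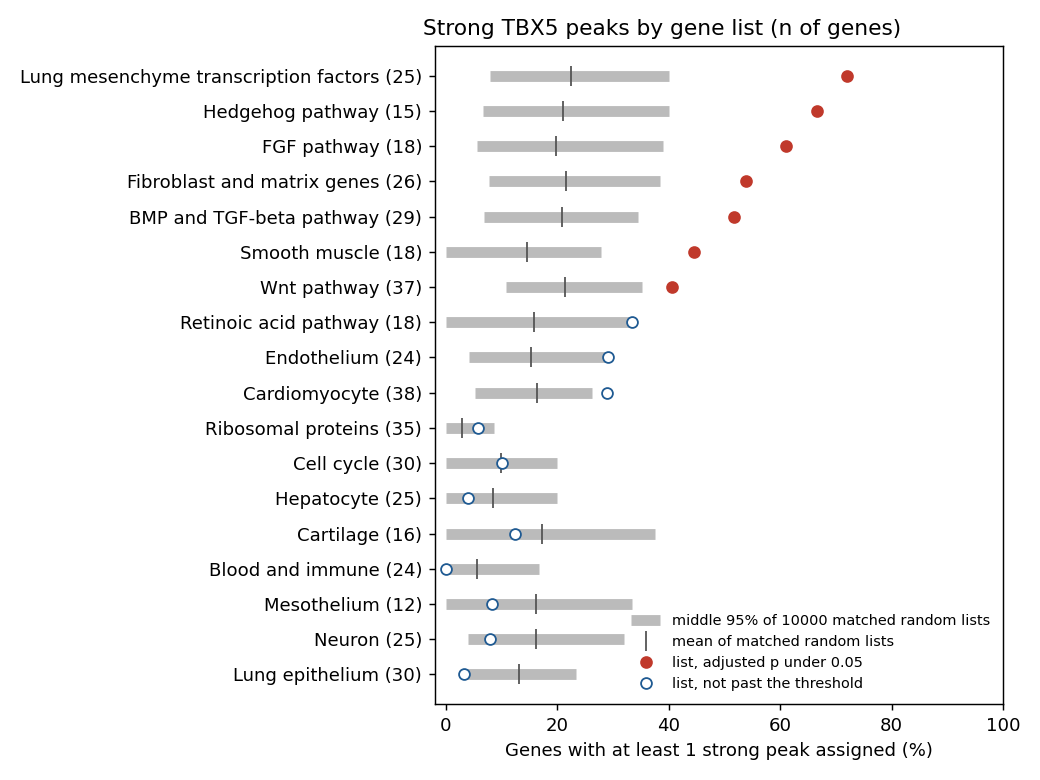
Share of each list's genes with at least 1 strong TBX5 peak (x axis, %; points), with the mean (tick) and the middle 95% (grey bar) of 10000 random lists matched on territory, for 18 lists (y axis; number of genes in brackets). Filled points, from 40.5% to 72%, mark the 7 lists past the adjusted threshold.

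Transcription factors of lung mesenchyme stood highest: 18 of 25 genes (72%) had a strong peak, against 22.4% in matched lists (middle 95%, 8 to 40%; adjusted permutation p = 0.0012). They included the 4 T-box genes and Foxf1, the forkhead factor of visceral mesenchyme, whose strongest peak lay 90.5 kb outside the gene on chromosome 8 from 120993665 to 120994162 (30.7-fold). Meis1 (19 peaks, 6 strong) and Pbx3 (14 peaks, 4 strong), TALE-class homeodomain factors, and Tcf21 (11 peaks, 3 strong) were named after their values were seen. Twist1, Osr2 and Nkx2-3, named on the same basis, had 0 peaks.

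Fibroblast and matrix genes had a strong peak in 14 of 26 cases (53.8% against 21.6%; adjusted permutation p = 0.00144). The fibrillar collagen genes Col5a2 (7 peaks, 3 strong, 36.8-fold at the strongest, on chromosome 1 from 45380027 to 45380913) and Col1a1 (6 peaks, 2 strong, 29.3-fold on chromosome 11 from 94896505 to 94897094) held the highest peaks of the list. Of the smooth muscle genes, 8 of 18 had a strong peak (44.4%, where the middle 95% of matched lists was 0 to 27.8%; adjusted permutation p = 0.0072). Caldesmon, Cald1, had 14 peaks, 5 of them strong, up to 63.6-fold on chromosome 6 from 34552355 to 34553038, and the integrin gene Itga8 had 20 peaks, 6 of them strong, up to 40.1-fold on chromosome 2 from 12109302 to 12109754. With the 1000 highest peaks in place of 5000, neither list passed the threshold (adjusted permutation p = 0.293 and 0.749). Their shares were then 15.4% against 5.53% in matched lists and 11.1% against 3.845%.

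Hedgehog pathway genes had a strong peak in 10 of 15 cases (66.7% against 21.0%; adjusted permutation p = 0.0012). The receptor gene Ptch1 had 22 peaks, 7 of them strong, the highest on chromosome 13 from 63558323 to 63558955 (19.2-fold). The co-receptor gene Boc had 17 peaks, the highest of 36.3-fold on chromosome 16 from 44538098 to 44539034, and the transcription factor gene Gli2 had 15, up to 39.4-fold inside the gene on chromosome 1 from 118976369 to 118977124. Gli1 and Hhip, both known targets of the pathway, had 4 peaks each, up to 7.50-fold and 9.89-fold, none of them strong (with a limit of 1 Mb, Hhip had 9 peaks). The counts of these genes were not scaled by territory, which was 13.7 kb for Gli1, 170.6 kb for Ptch1, 286.5 kb for Hhip and 374.4 kb for Gli2. Among the 14191 highest peaks, Ptch1 had 13, Boc 10, Gli2 9, Hhip 2 and Gli1 1. The ligand gene Shh, made by the epithelium, had 0 assigned peaks. With the 1000 highest peaks, 26.7% of the list had a peak against 5.72% in matched lists, and the adjusted permutation p was 0.0648.

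In the FGF pathway, 11 of 18 genes had a strong peak (61.1% against 19.8%; adjusted permutation p = 0.0012), and all 18 had a peak of any strength. The receptor gene Fgfr2 had 14 peaks, up to 42.5-fold on chromosome 7 from 130278500 to 130279613, outside the gene (22 peaks with a limit of 1 Mb). Dusp6, a phosphatase gene induced by FGF signalling, had 5 peaks, up to 24.6-fold. Fgf10, the mesenchymal ligand that drives branching, had 8 peaks, none strong, and 8.93-fold at the one with the highest −log10 q. Of the BMP and TGF-beta genes, 15 of 29 had a strong peak (51.7% against 20.9%; adjusted permutation p = 0.00144). Tgfbr3 (22 peaks, 5 strong) and Smad5 (5 peaks, 21.2-fold at the strongest) held the highest peaks of that list, and Bmp4 had 2 peaks, up to 5.68-fold, none strong (6 peaks with a limit of 1 Mb). Of the 14191 highest peaks, 8 were assigned to Fgfr2, 2 to Dusp6, 5 to Fgf10, 3 to Smad5 and 1 to Bmp4. With the 1000 highest peaks, 0% of the BMP and TGF-beta genes had a peak.

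Wnt pathway genes had a strong peak in 15 of 37 cases (40.5% against 21.4%; adjusted permutation p = 0.0298). Wnt11 (8 peaks, 3 strong, 17.8-fold) and Nkd1, an inhibitor of the pathway (7 peaks, 1 strong, 24.7-fold), held the peaks with the highest −log10 q of the list. Sfrp2, Rspo2 and Fzd1, whose peaks with the highest −log10 q had 20.2, 19.8 and 17.9-fold enrichment, were named after their values were seen. Wnt2 and Wnt2b, the mesenchymal ligands that specify the lung, had 3 peaks, none strong, and 2 peaks, of which 1 was strong and lay 1.30 kb outside Wnt2b on chromosome 3 from 104962413 to 104963233 (17.7-fold). This call ended under 4 other settings. With the 1000 highest peaks the share was 5.41% against 6.07% (adjusted permutation p = 1). With strong peaks within 10 kb of a gene end it was 18.9% against 7.87% (adjusted permutation p = 0.117). Ranked by fold it was 37.8% against 20.9% (adjusted permutation p = 0.0576), and without gene-end peaks 35.1% against 20.8% (adjusted permutation p = 0.115).

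Retinoic acid pathway genes did not pass the threshold with strong peaks: 6 of 18 had a strong peak (33.3% against 15.9%; adjusted permutation p = 0.159). Aldh1a2, which makes retinoic acid in lung mesenchyme, had 6 peaks, 2 of them strong. The highest lay inside the gene on chromosome 9 from 71262716 to 71263111, 33.4 kb from its nearer end (36.9-fold). Rxrg, a retinoid receptor gene, had 4 peaks, up to 32.4-fold at a gene end on chromosome 1 from 167598293 to 167598860. Rdh10, which makes retinaldehyde, had 4 peaks, up to 7.45-fold, none strong. Counting peaks of any strength, 16 of the 18 genes had a peak (88.9% against 48.5%; adjusted permutation p = 0.00144).

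Genes of lung epithelium carried few strong peaks, but the list did not pass the threshold for lying below matched lists. Of 30 genes, 1 had a strong peak (3.33% against 13.1% in matched lists; adjusted permutation p = 0.215), Foxa2 (2 peaks, 20.7-fold; 6 peaks with a limit of 1 Mb). Counting peaks of any strength, 11 of the 30 had a peak (36.7% against 43.0%; adjusted permutation p = 0.686). Esrp1, an epithelial splicing factor gene, had 1 peak of 11.5-fold, and Nkx2-1, the transcription factor of lung identity, had 0. Cardiomyocyte genes had a strong peak in 11 of 38 cases (28.9% against 16.3%; adjusted permutation p = 0.112). Gata6 had 6 peaks (39.6-fold at the strongest; 14 with a limit of 1 Mb), Myl3 6 (34.9-fold, at a gene end), Gata4 5 (17.7-fold), Nkx2-5 2 (15-fold) and Nppa 0. Their territories ran from 9.2 kb for Nppa to 233.1 kb for Gata6, and the counts were not scaled by them. The cardiomyocyte list passed the threshold with the 1000 highest peaks (18.4% against 4.47%; adjusted permutation p = 0.0144) and under 3 other settings, with adjusted permutation p from 0.0138 to 0.0365. Of the endothelial genes, 7 of 24 had a strong peak (29.2% against 15.3%; adjusted permutation p = 0.170), among them Flt1 (17.6-fold) and Tek (22.1-fold).

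The lists of other tissues and of genes used in every cell did not depart from matched lists with strong peaks. A strong peak was assigned to 1 of 12 mesothelial genes (Upk1b, 31.8-fold; Podxl had 1 peak, not strong), 2 of 16 cartilage genes (Sox6, 29.3-fold, and Col2a1, 14.8-fold), 2 of 25 neuronal genes (Gap43 and Nefm), 1 of 25 hepatocyte genes (Fgg, 32.5-fold; Ttr had 2 weaker peaks and Alb 0), 2 of 35 ribosomal protein genes (Rpl3, 15.6-fold, and Rpl27, 13.5-fold) and 3 of 30 cell cycle genes (E2f3 and Mycn among them; Mycn had 5 peaks, or 10 with a limit of 1 Mb). The adjusted permutation p ranged from 0.561 for neurons to 1 for cell cycle genes. None of the 24 blood and immune genes had a strong peak (0% against 5.68%; adjusted permutation p = 0.606), and 2 of them, Ptprc (3 peaks, or 11 with a limit of 1 Mb) and Cd8a, had weaker peaks. With peaks of any strength, the cell cycle list (73.3% against 36.3%; adjusted permutation p = 0.0012) and the ribosomal protein list (42.9% against 22.6%; adjusted permutation p = 0.0194) lay above matched lists, and the blood and immune list lay below (8.33% against 29.8%; adjusted permutation p = 0.0268). The ribosomal share is below the 48.6% with a peak at an end. A peak at an end counted for every gene within 1 kb, whichever gene it was assigned to.

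Mesenchymal lists differed from the epithelial list when compared directly. The share with a strong peak was 68.7 percentage points higher for lung mesenchyme transcription factors than for lung epithelium, where matched random lists differed by 9.07 points (middle 95%, −9.33 to 28.7; adjusted permutation p = 0.00053, and adjusted p = 4.16e-07 in Fisher's exact test). Fisher's exact test takes no account of territory, whose median was 145 kb for the mesenchyme factors and 66.0 kb for the epithelial list. Both tests treat genes as independent. Fibroblast and matrix genes were 50.5 points and smooth muscle genes 41.1 points above the epithelial list (adjusted permutation p = 0.00053 and 0.00064). The cardiomyocyte and endothelial lists were 25.6 and 25.8 points above it (adjusted permutation p = 0.00709 and 0.0082). The mesenchyme factors were 43.1 points above the cardiomyocyte list and 42.8 above the endothelial list, and fibroblast and matrix genes 41.3 above cartilage (adjusted permutation p = 0.00064, 0.00053 and 0.0024). These 8 pairs were chosen after the results of the single lists had been seen.

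Chromosome X carried few peaks for its length. Its 415 peaks came to 2.43 per Mb (exact 95% Poisson interval 2.20 to 2.67), while the 19 autosomes ranged from 9.68 per Mb on chromosome 12 to 15.6 on chromosome 11, with 11.5 over all of them. Per protein-coding gene, chromosome X had 0.430 peaks (0.389 to 0.473) and the autosomes 0.769 to 2.36. The median fold was 6.13 on chromosome X and 6.27 on the autosomes. These intervals cover counting error only.

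**Figure D4:**
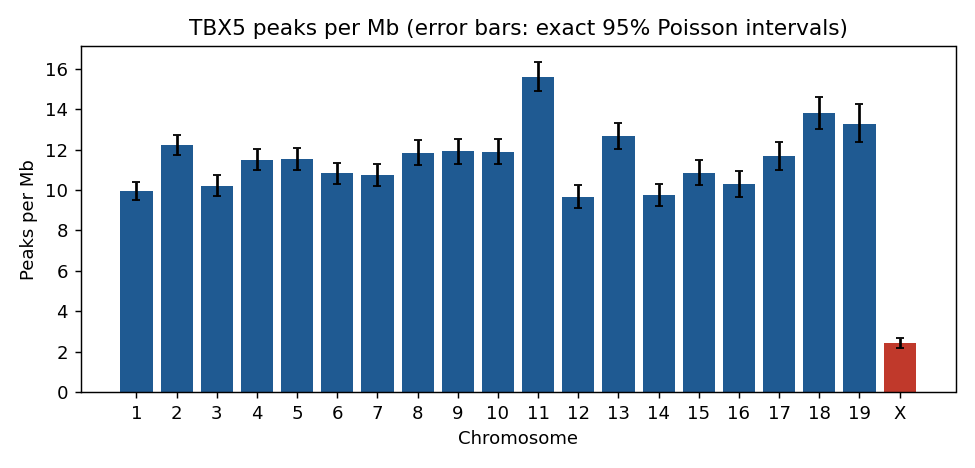
TBX5 peaks per Mb (y axis) on each chromosome (x axis), with exact 95% Poisson intervals as error bars. Chromosome X, in red, stands at 2.43 and every autosome at 9.68 or more.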

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

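Among the alternatives, those ranked by fold, by nearest gene body, without gene-end peaks, by a binomial test and with placements near genes were chosen after the results had been seen, as were the tests of fold by position and of differences between lists. No paired analysis was possible because 1 list was deposited for all libraries, with no value per library, and for the same reason no replicate could be left out. The shares at gene ends and inside genes, the median distance and the closeness of peaks kept their direction and their side of the threshold under every alternative run. Placements near genes were run for the gene-end share only, so no alternative changed where random positions could fall for the other measures. The stricter peak count was 14191. Lists above matched lists numbered 3 with the 1000 highest peaks, of which 2 were among the original 7, and 6 to 10 under the other 9 settings. Lists below numbered 1 with all peaks and 0 under the other settings. With the 1000 highest peaks, the Wnt list turned to 5.41% against 6.07% and the BMP and TGF-beta list to 0% against 5.37%; that setting leaves fewer genes with a peak, and the cause was not tested further. Added calls came from the cardiomyocyte list under 4 settings, the retinoic acid list under 3, and the endothelial, cell cycle and ribosomal protein lists under 1 each. The Wnt list was the only list that lost its call under another setting than the 1000 highest peaks. Of 66 named genes, the number of assigned peaks moved by over 1.5 times for 13 with a limit of 1 Mb, 3 with the nearest gene body and 39 with the stricter peaks, where a count of 50% follows from the size of the list. Of the named genes with over 20 peaks, Nfib (33 to 15), Tbx5 (30 to 11) and Zeb2 (23 to 9) fell further. Outside the genes whose stricter counts are given in the report, the 39 included Itga8 (13 left), Sox6 (6), Wnt11 (4), Nkd1 (4), Gata6 (3), Myl3 (3), Mycn (3), Gata4 (2), Nkx2-5 (1), Wnt2 (1), Wnt2b (1), Rdh10 (1), Gap43 (1), Ttr (1) and Cd8a (0). Not run were all alternatives of the motif tests, which need a genome sequence, and matching on GC content. The stricter list left the strong peaks as they were and so gave no value for the gene lists. The unknown depth limits which weak peaks were called.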

Other observations

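The tests of families, gene types, both ends of genes and contractile genes, and the dense windows, were chosen after the deposited list had been seen, and the families and the contractile list before their own results. The 5 tests of explanations had their outcomes stated before those outcomes were known.

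Hox genes, the clustered regulators of position along the body axis, had a larger share of genes with a strong peak than random lists matched on their short territories: 10 of 39 (25.6% against 3.05%; permutation p adjusted over 17 families = 0.00113). The densest 100-kb window of the genome lay over the Hoxb cluster, with 42 summits on chromosome 11 from 96260556 to 96354421, of which 18 were assigned to Hoxb4 and 13 to Hoxb3. The next held 33 summits over the Hoxa cluster on chromosome 6 from 52158404 to 52234207. Dense windows also lay over Tbx5 (28 summits), Bcas3 (26), Tbx2 with Tbx4 (21) and Ptch1 (21). At the other end, 5 of 1110 olfactory receptor genes (0.450% against 4.11%) and 0 of 353 vomeronasal receptor genes (0% against 8.85%) had a strong peak, both with an adjusted permutation p of 0.00113. Genes of these 3 families lie side by side in clusters, while the random lists draw genes independently, so these p-values are too small by an amount that was not measured. The other 14 families, collagens (15 of 44 genes; adjusted permutation p = 0.196), T-box genes, forkhead genes, SOX genes, integrins, semaphorins, ADAMTS proteases, zinc finger genes, keratins and histones among them, did not pass the threshold.

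Peaks also lay at the ends of transfer RNA genes. In all, 107 of 408 tRNA genes (26.2%) had a summit within 1 kb of an end, against 2.39% in random placements. For protein-coding genes the share was 22.6% against 4.29%. The ratios to placement, 10.96 and 5.26, cannot be compared directly, since random placement itself reached protein-coding genes more often. Of 341 tRNA genes over 2 kb from protein-coding gene ends, 69 (20.2%, exact 95% binomial interval 16.1 to 24.9%) had a summit within 1 kb, against 2.36% in random placements (adjusted permutation p = 0.00289). The same shares were 8.37% against 4.35% for long non-coding RNA genes, 4.26% against 2.23% for microRNA genes, 1.15% against 3.13% for pseudogenes, 0.683% against 2.32% for small nucleolar RNA genes and, with no difference detected, 2.57% against 2.27% for small nuclear RNA genes (adjusted permutation p = 0.605). Without that filter, small nuclear RNA genes stood at 3.49% against 2.27% (adjusted permutation p = 0.0354), small nucleolar RNA genes at 1.94% against 2.33% (adjusted permutation p = 0.506), long non-coding RNA genes at 11.8% against 4.35%, microRNA genes at 6.84% against 2.27% and pseudogenes at 1.33% against 3.15% (adjusted permutation p = 0.00289 for these 3). The 86 peaks at tRNA genes had a median fold of 5.51, and 3 of them were strong. Fewer peaks than genes stand behind these shares, 86 for the 107 tRNA genes and 49 for the 69, so 1 peak could count for several genes. The binomial interval for tRNA genes treats them as independent and is therefore too narrow, by an amount that was not measured. Among 5453 protein-coding genes over 20 kb long and apart from other genes, 1246 had a summit at 1 end only and 30 at both ends, where independent ends would give 78.2 (Fisher's exact test p = 1.32e-11).

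The excess of peaks within 1 kb of gene ends was set against 2 technical explanations. Placement of random positions in gene-poor or unmappable sequence would leave summits as dense from 1 to 5 kb as within 1 kb of the same ends, but the density was 5.65 times higher within 1 kb (95% interval 5.39 to 5.92), which argues against that as the whole cause. Capture of active promoters irrespective of TBX5 predicts peaks at genes used in every cell, and 48.6% of ribosomal protein genes had a peak at an end, against 21.9% in matched lists (middle 95%, 8.57 to 37.1%; permutation p = 0.0004). Such capture may therefore account for part of the weak gene-end peaks, and those at tRNA genes could belong to them, which was not tested. Binding of TBX5 at active promoters would give the same values, and neither a ChIP in tissue without TBX5 nor the T-box motif was examined here.

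The low number of peaks on chromosome X was set against 2 explanations. Gene density as the whole cause would bring chromosome X into the range of the autosomes per gene, but it had 0.430 peaks per protein-coding gene (exact 95% Poisson interval 0.389 to 0.473), below the lowest autosome at 0.769. A single X copy in male embryos could lower fold enrichment by at most the ratio of copies. Peaks of 10-fold on chromosome X should then be at least as frequent as peaks of 20-fold on the autosomes. Equal numbers are predicted only if all embryos were male and the fold was lowered by the full ratio. A smaller lowering predicts more, up to the autosomal 28.8 per 100 genes at 10-fold. Chromosome X had 6.73 per 100 genes at 10-fold (5.19 to 8.58) and the autosomes 7.15 at 20-fold. The counts are too few to decide on the full ratio, and this remains open. The sex of the embryos was not among the labels used here, and no biological explanation was tested.

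The source field that names heart for ChIP library 2 was followed up with the 17 contractile and natriuretic genes of the cardiomyocyte list, none of which stands in another list. Heart tissue predicts strong peaks near them, and 3 of 17 had such a peak (17.6% against 8.55%, middle 95% 0 to 23.5%; permutation p = 0.292), Myl3 (34.9-fold), Ryr2 (29.5-fold) and Actc1 (17.9-fold). With peaks of any strength it was 7 of 17 (41.2% against 33.4%; permutation p = 0.624), and Nppa, Nppb, Tnnt2, Myh6, Ttn and Myl7 had 0. With so few genes, heart tissue in that library cannot be told apart from lung alone under a wrong source field. Cardiac muscle also surrounds the pulmonary veins of the mouse, so strong peaks near such genes could come from lung samples too.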
